A study of Mus musculus with 18 samples.

How the data were processed

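Total lung RNA of 12 mice and RNA of 6 PMVEC samples was hybridised to Illumina mouse bead arrays, 1 array per sample. Per the labels, RNA was extracted with Trizol and purified on columns, and biotinylated copies were made with a commercial amplification kit. BeadStudio is named in the submitters' processing notes, without a version, and the chip on which each array lay is not given in the sources used here. The authors deposited non-normalized tables that hold, for each probe and array, a signal intensity and a detection p-value, which states how likely a signal of that size is among negative control beads. They also deposited a table of log2 values for all arrays. Set against the non-normalized signals, this table held the log2 of the signal with each array shifted to a common median. Within a tolerance of 0.02 log2, 25697 of 25697 probes matched in the lung arrays, whereas 7582 probes (29.5%) did not match in the PMVEC arrays. All 7582 were found under another probe, for 7049 of them one of the same gene symbol. Across those probes the non-normalized PMVEC signal correlated with the mean lung signal at r = 0.804 and the values of the log2 table at r = 0.368, against 0.807 for matching probes, so the non-normalized tables were used and the log2 table served as an alternative.

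Probes were named from the platform annotation. Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none; 23962 gene numbers were found in a table of the GRCm38.p6 assembly, which changed 0 symbols. A probe without a symbol was tested, and counted, as a gene of its own. Such probes made up 127, 93, 0, 77, 0 and 18 of the genes that passed in the 6 comparisons listed further on. The files name no genome build, so the reference table served only for names and for the distance between genes. Probes of Il4ra and Il2rg were not analysed here, and Sele was tested in neither experiment. Il4, Retnla, Epas1, Apln, Arg1, Chil3, Hmgb1 and Bmpr2 were tested in lung but were too dim in PMVEC.

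Signals were processed in R 4.3.3 with limma 3.58.1. The neqc function estimated the background of each array from the detection p-values, added an offset of 16, quantile normalized the arrays and took log2, separately for the 12 lung and the 6 PMVEC arrays. This compresses the fold changes of dim probes and assumes that most genes keep the same overall distribution of signals. Probes with a detection p under 0.05 on at least 3 arrays were kept, 17112 in lung and 11947 in PMVEC. Each gene was represented by its probe of highest mean value, giving 12571 and 9017 genes. A gene whose lower group was detected on none of its arrays is given as "at least N-fold", the brighter group's mean against the mean of, per array, the higher of the lowest detected signal and the probe's own value. Linear models (lmFit and eBayes) were fitted over the 4 lung groups and over the 2 PMVEC groups, with 8 and 4 residual degrees of freedom and 4.27 and 7.48 prior degrees of freedom. All p-values are two-sided, and adjusted p-values are those of Benjamini and Hochberg at 0.05 over the genes of a comparison.

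The 6 comparisons were hypoxia in wild-type lung, hypoxia in knockout lung, the difference between these, the genotypes in room air, the genotypes under hypoxia, and recombinant IL-4 in PMVEC. The comparisons, the tests, 32 gene lists, the rule for named genes and all alternatives but the last pair were chosen before the data were examined. The rule took the 8 largest rises and 8 largest falls among passing genes whose groups did not overlap, up to 4 passing members per list with the largest change, and the genes fixed for this study; where fewer than 10 genes passed, it took all of them and the 5 next smallest p-values. Of the genes this rule gave, the text names chiefly those whose call held on leaving out each array. Sex-linked transcripts were not chosen; 3 Y-linked probes, of which at least 1 was detected on 12 of 12 lung arrays and on 0 PMVEC arrays, matched the sexes that the labels give.

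Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 174 combinations of list and comparison, and again with the correlation estimated from the data. Called lists numbered 16, 14, 7, 10, 16 and 4 in the 6 comparisons, of which 1, 3, 0, 0, 1 and 0 held with the estimated correlation. Angiogenesis, alveolar macrophage, mast cell and basophil, erythroid, alveolar type 1 cell and lymphatic endothelial lists passed in no comparison, and the eosinophil list, with 3 measured genes, was not tested. A list of 40 liver genes was added after liver transcripts were seen among the calls.

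The procedure was tested on simulated values built from the lung and PMVEC arrays. Noise was drawn independently for each gene, with 1 draw per comparison. The shares below therefore leave out correlation between genes, and differences between comparisons of like design can come from the draw. Log2 changes of size 0.5, 1 and 2 were given to 50, 100 and 50 genes. Recovery at an adjusted p depends on how many genes change, so the shares need not hold where many more did. At a true log2 change of 1, it recovered 82% of changed genes for hypoxia in wild type, 93% for hypoxia in the knockout, 52% for the interaction, 90% for genotype in room air, 93% for genotype under hypoxia and 100% for PMVEC. At 0.5 it recovered 16%, 26%, 4%, 12%, 20% and 64%. False calls were between 4.58% and 5.70% of calls. Lung RNA came from separate mice, whereas nothing states that the PMVEC replicates were separate cultures, so the p-values in PMVEC measure only the spread between these samples, which may be technical.

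Alternatives were no background correction, a median shift in place of quantile normalization, all 18 arrays normalized together, no filter or a stricter filter on dim probes, every probe on its own, the deposited log2 table, a trended and robust variance, array weights, only the groups compared, and leaving out each array in turn. After the data were seen, a last pair was added, the mean liver level as a covariate and the omission of KO normoxia 1 and 2.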

Results

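Gene expression was measured on 18 Illumina mouse bead arrays, on which beads carry short probes and the brightness of a probe reads the abundance of its transcript. Of these, 12 arrays held total lung RNA of wild-type or interleukin-4 (IL-4) knockout male mice that breathed 10% oxygen or room air for 4 days, with 3 animals in each of 4 groups. The other 6 arrays held RNA of cultured pulmonary microvascular endothelial cells (PMVEC) of female mice, treated for 24 h with recombinant IL-4 at 50 ng/mL or with vehicle, with 3 samples per condition. IL-4 is a cytokine of type 2 immunity. The groups are called WT normoxia, WT hypoxia, KO normoxia, KO hypoxia, vehicle and rIL-4, with a replicate number for each array. Between 60.2% and 64.2% of probes were detected on a lung array and between 45.1% and 46.9% on a PMVEC array, and the median raw signal was 126 to 152 in lung and 52.3 to 59.4 in PMVEC. The correlation of log2 values between arrays of a group, taken across probes, which are not independent replicates, lay between 0.980 and 0.995. No pair of arrays within a group held identical values, and pairs from different groups were not checked for this. The number of arrays limits the precision of every value. Lung and PMVEC values were normalized separately, so no test was made between them, and raw signals of both were set side by side only to describe marker genes and to check probes.

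The Il4 gene itself was read by 1 probe. Its normalized log2 signal was 8.26, 8.13 and 7.67 in WT normoxia, 7.64, 7.28 and 7.25 in WT hypoxia, 5.72, 4.97 and 5.63 in KO normoxia, and 5.86, 5.37 and 5.58 in KO hypoxia, so all 6 knockout arrays lay below all 6 wild-type arrays. In the knockout the probe was detected on 2 of 3 arrays in each oxygen condition. Whether the probe lies within the deleted part of the gene is not given in the sources used here. If it lies outside, these values do not check the genotype labels.

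**Figure D1:**
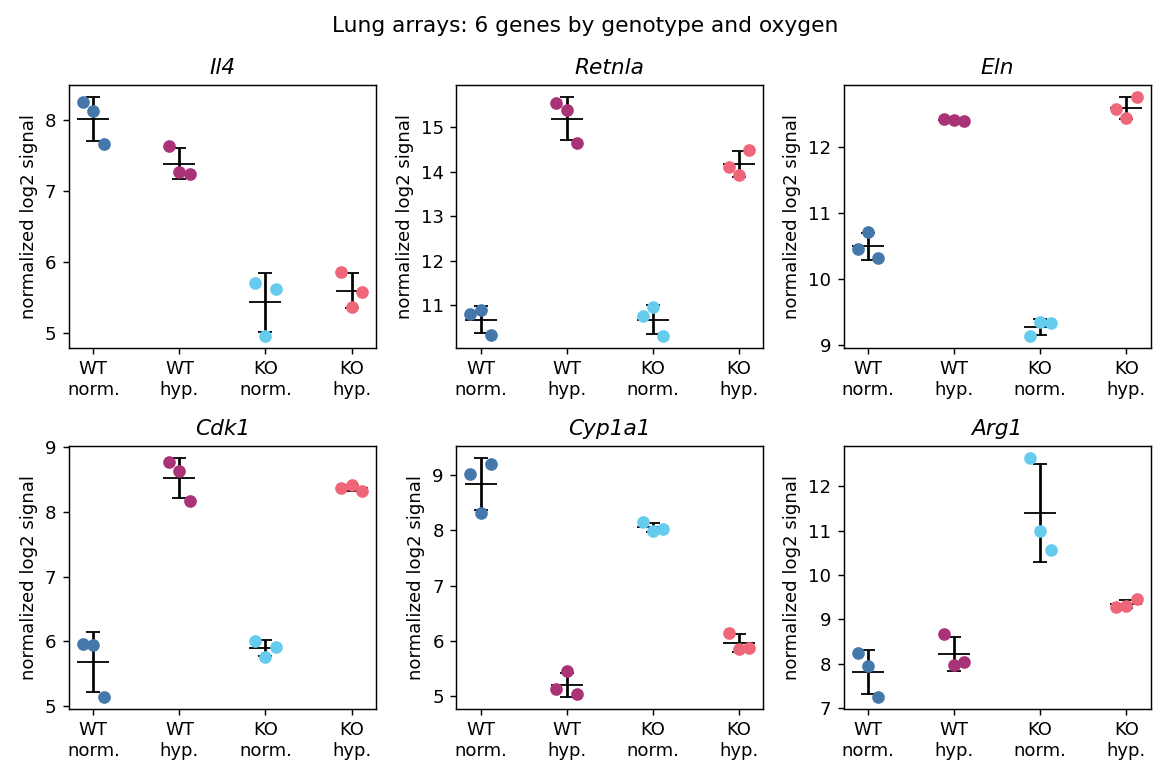
Normalized log2 signal of Il4, Retnla, Eln, Cdk1, Cyp1a1 and Arg1 on each lung array (points), by group, with the group mean (horizontal line) and SD (bars), n = 3 arrays per group. Il4 lay lower in both knockout groups, Retnla rose with hypoxia from 10.68 to 15.20 in wild type and from 10.67 to 14.18 in the knockout, and Arg1 stood highest in KO normoxia at 11.40.

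The first comparison asked what 4 days of hypoxia changed in wild-type lung. Saa3, an acute-phase serum amyloid, rose 26.4-fold, from 7.33 ± 0.78 to 12.06 ± 1.77 on the log2 scale (SD, n = 3). Retnla, a secreted protein of alternatively activated macrophages and airway epithelium, rose from 10.68 ± 0.30 to 15.20 ± 0.49 (log2 change 4.52, SE 0.25, adjusted p = 2.3e-06). Of 31 cell cycle genes 26 rose, and of 36 extracellular matrix genes 25 rose and 3 fell (adjusted p = 0.074 and 0.0069 with an estimated correlation). Cdk1, the mitotic kinase, went up from 5.68 ± 0.46 to 8.52 ± 0.31 and Col1a1, a chain of type I collagen, from 9.40 ± 0.04 to 11.84 ± 0.36. Cyp1a1, a target of the aryl hydrocarbon receptor, dropped from 8.84 ± 0.47 to 5.21 ± 0.21, a 12.4-fold fall.

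Among other large rises in wild-type lung were Ntrk2, the receptor of brain-derived neurotrophic factor (log2 change 3.81, from 7.34 ± 0.60 to 11.15 ± 0.15), Ltf, the iron-binding lactoferrin (13.4-fold), Ptx3, a soluble pentraxin (9.61-fold), Ccl8, a monocyte chemokine (8.43-fold), and Gxylt2, a xylosyltransferase (7.56-fold). Gp2 lay at least 9.11-fold higher, because it was detected on no WT normoxia array. The largest falls beside Cyp1a1 were those of Npr3, the clearance receptor of natriuretic peptides (10.1-fold, from 12.06 ± 0.13 to 8.72 ± 0.11), and Igfbp3, a binding protein of insulin-like growth factors (4.90-fold). Among the genes named in advance for this study, Epas1, which encodes HIF-2 alpha, fell by 0.99 on the log2 scale (adjusted p = 0.0002). Il4 changed by -0.63 (adjusted p = 0.088), Vegfa by -0.14 (0.58), Vcam1 by 0.31 (0.098), Selp by 0.57 (0.10) and Arg1 by 0.41 (0.61), none of which passed.

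The lists fixed in advance gave this account of wild-type lung under hypoxia. Of 31 measured cell cycle genes, 26 rose and 5 did not pass, and 30 rose when adjusted over the list alone. Examples were Cdk1 (log2 change 2.84), Tk1 (2.54), Ccna2 (2.42) and Tpx2 (2.30), and the list had a camera adjusted p = 3.6e-28, with adjusted p = 0.074 with an estimated correlation. Extracellular matrix was the list whose call held both ways. Of its 36 measured members 25 rose, 3 fell and 8 did not pass, and adjusted over the list alone there were again 25 and 3 (camera adjusted p = 6.8e-16, and adjusted p = 0.0069 with an estimated correlation). Timp1 (2.76), Col1a1 (2.44), Tnc (1.93) and Eln, which encodes elastin (1.92), led it. Endothelial activation had 7 risen, 3 fallen and 13 not passing of 23, and 9 and 4 adjusted over the list alone. Cxcl5 (2.31), Il6 (at least 3.32-fold), Ccl7 (1.88) and Ccl2 (1.27) were among the rises (camera adjusted p = 0.045, and adjusted p = 0.46 with an estimated correlation). Of 27 interferon genes 6 rose, or 8 adjusted over the list alone, and 21 did not pass. They included the chemokines Cxcl9 (2.10) and Cxcl10 (at least 2.48-fold), with a camera adjusted p = 2.6e-05 and adjusted p = 0.46 with an estimated correlation.

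Several stress and hormone lists shifted in the same tissue. Among 15 glucocorticoid response genes 9 fell, Pdk4 by 1.95 on the log2 scale, and 6 did not pass, with 9 fallen and 1 risen adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.27 with an estimated correlation). Immediate early genes fell in 7 of 16, with 9 not passing, and 8 fallen and 1 risen adjusted over the list alone. Fosb fell by 1.57 and Ccn1 by 1.36 (camera adjusted p = 0.00035, and adjusted p = 0.14 with an estimated correlation). The endoplasmic reticulum stress list had 2 of 18 fallen, Creld2 by 1.02 and Hspa5 by 0.56, and 9 adjusted over the list alone (camera adjusted p = 3.7e-05, and adjusted p = 0.27 with an estimated correlation). Sterol synthesis went up in 7 of 12 genes, or 9 adjusted over the list alone, with Stard4 at 0.73 and Fdps at 0.68 (camera adjusted p = 3.1e-05, and adjusted p = 0.31 with an estimated correlation). The hypoxia and HIF target list did not pass, with 8 of its 31 members risen, among them the glycolytic genes Pfkl (0.74) and Aldoc (0.71), and 2 fallen (camera adjusted p = 0.29). Nor did angiogenesis (28 measured, 5 risen, 5 fallen, camera adjusted p = 0.99), type 2 response (24 measured, 4 risen, 2 fallen, 0.29) or smooth muscle contractile genes (9 measured, 3 risen, 0.054). Vegfc (1.22), Cxcl12 (1.45), Tagln (0.89) and Acta2 (0.76) rose singly, and Dll4, the Notch ligand of tip cells, fell by 1.14.

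Markers of cell types moved as well. Of 21 endothelial markers 1 rose, Emcn at 1.26, 7 fell, with Plvap falling by 1.59 and Eng by 1.30, and 13 did not pass. Adjusted over the list alone, 2 rose and 11 fell (camera adjusted p = 0.00056, and adjusted p = 0.27 with an estimated correlation). Fibroblast and mesenchymal markers rose in 6 of 16, or 8 adjusted over the list alone, with Col3a1 (1.72), Col1a2 (1.61) and Mfap4 (1.34) leading (camera adjusted p = 0.00018, and adjusted p = 0.23 with an estimated correlation). Monocyte and macrophage markers rose in 5 of 11, the same number adjusted over the list alone, among them Ms4a7 (1.69), C1qb (1.19) and C1qc (1.15) (camera adjusted p = 0.0043, and adjusted p = 0.33 with an estimated correlation). B cell markers rose in 1 of 10, or 5 adjusted over the list alone (camera adjusted p = 0.0062, and adjusted p = 0.47 with an estimated correlation). T cell markers did so in 2 of 10, also adjusted over the list alone, with Thy1 at 1.11 (camera adjusted p = 0.014, and adjusted p = 0.52 with an estimated correlation). Mesothelial markers rose in 2 of 8 by either count (camera adjusted p = 0.028, and adjusted p = 0.33 with an estimated correlation). Neutrophil markers fell in 4 and rose in 1 of 10, with 5 fallen and 2 risen adjusted over the list alone (camera adjusted p = 0.047, and adjusted p = 0.62 with an estimated correlation). Cxcr2 fell by 2.28, S100a9 by 2.01 and S100a8 by 1.99, and these calls were lost without WT normoxia 1 or 2 or any WT hypoxia array, S100a9 also without any knockout array, with adjusted p of up to 0.111, 0.137 and 0.113 over the alternatives. The mean deviation of all measured neutrophil markers was 1.59, 0.77 and -0.72 in WT normoxia against -0.17, -0.13 and -0.21 in WT hypoxia, so that WT normoxia 3 lay below all hypoxic arrays. Adipocyte markers fell in 1 of 5, or 3 adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.46 with an estimated correlation), and WT hypoxia 1 stood apart in them, at -1.19 against -0.01 and 0.16. The neutrophil and adipocyte calls were also lost with the mean level of liver genes as a covariate, at adjusted p = 0.34 and 0.072.

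In all, 1483 of 12571 genes passed at an adjusted p of 0.05 with limma, 940 up and 543 down, and 3231 had an unadjusted p under 0.05. At least 2-fold changes were 303 rises and 92 falls among them. The 3 values of one group lay wholly above or below the other in 99.1% of the passing genes and in 28.9% of all genes, where chance gives 10%. Here and in the comparisons below, the share among passing genes follows largely from their selection, and only that of all genes can be set against chance. The count was 922 without WT normoxia 1, 890 without WT normoxia 2, 910 without WT hypoxia 1 and 984 without WT hypoxia 2. The Gp2 call was lost without WT normoxia 1 or 2 or WT hypoxia 2 or 3, with an adjusted p of up to 0.0684 over the alternatives.

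The same exposure in the IL-4 knockout was the next comparison. Ntrk2 rose 14.4-fold, from 7.25 ± 0.41 to 11.10 ± 0.11, and Retnla 11.3-fold, from 10.67 ± 0.33 to 14.18 ± 0.28 (SD, n = 3; log2 change 3.50, SE 0.25, adjusted p = 8.3e-06). Eln rose 10.0-fold, from 9.27 ± 0.12 to 12.60 ± 0.16 (log2 change 3.33, SE 0.13, adjusted p = 6.3e-08). All 31 measured cell cycle genes rose. Of 36 measured genes that the liver transcribes at high levels 33 fell, and KO normoxia was the lung group in which those genes stood highest.

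Pbk, a mitotic kinase (3.03), Ptx3 (2.99), Tnc, the matrix glycoprotein tenascin C (2.78), and Ccl8 (2.21, adjusted p = 8.5e-05) were further large rises on the log2 scale. The largest falls were mostly of liver transcripts, among them Cyp2a5 (-2.90), Hpx, the heme-binding hemopexin (-2.84), Saa2 (-2.72), Fga, a chain of fibrinogen (-2.66), and Apoa1, the main protein of high-density lipoprotein (-2.60). Of 36 measured liver genes, from a list of 40 drawn up after liver transcripts were seen among the calls, 33 fell in this comparison, with a median of -2.00. The KO normoxia arrays, on which these genes stood highest, enter both this comparison and that of the genotypes in room air. Arg1, the arginase of liver and of alternatively activated macrophages, fell by 2.06 (adjusted p = 0.010). The calls of Cyp2a5, Hpx, Saa2, Fga, Apoa1 and Arg1 were lost with the liver level as a covariate, and that of Hpx also without KO normoxia 1, KO hypoxia 1 or KO hypoxia 2. Of the genes named in advance, Epas1 fell by 0.70 (adjusted p = 0.0031) and Nos3, the endothelial nitric oxide synthase, rose by 0.88 (adjusted p = 0.0047).

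Cell cycle members rose in 31 of 31, by either count, including adjusted over the list alone, with Prc1 (2.64), Top2a (2.55), Cdk1 (2.47) and Ccna2 (2.45) as examples (camera adjusted p = 4.0e-37, and adjusted p = 0.044 with an estimated correlation). In the extracellular matrix list, 26 of 36 rose, 1 fell and 9 did not pass, or 26 and 2 adjusted over the list alone. Tnc, Col1a1 (2.13) and Timp1 (2.05) stood beside Eln (camera adjusted p = 1.6e-18, and adjusted p = 0.0069 with an estimated correlation). Immediate early genes were the other list to hold both ways. Of 16 members 7 fell and 9 did not pass, or 11 fell adjusted over the list alone, with Fosb falling by 2.06, Ccn1 by 1.40, Atf3 by 1.39 and Egr1 by 1.34 (camera adjusted p = 3.3e-09, and adjusted p = 0.027 with an estimated correlation). Smooth muscle contractile genes rose in 4 of 9 by either count, with Tagln at 1.33 and Acta2 at 0.70 (camera adjusted p = 0.00017, and adjusted p = 0.27 with an estimated correlation). Hypoxia and HIF targets rose in 4 of 31, or 6 adjusted over the list alone, with Pfkl at 0.75 and Gapdh at 0.46 (camera adjusted p = 0.048, and adjusted p = 0.27 with an estimated correlation). Interferon genes rose in 3 of 27, or 6 adjusted over the list alone, Tap1 at 0.77 among them (camera adjusted p = 2.3e-05, and adjusted p = 0.46 with an estimated correlation). Glucocorticoid response genes fell in 2 of 15, or 5 adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.42 with an estimated correlation). Sterol synthesis genes rose in 2 of 12 by either count, with Stard4 at 0.85 (camera adjusted p = 0.020, and adjusted p = 0.53 with an estimated correlation). Type 2 response (24 measured, 4 risen, 2 fallen, camera adjusted p = 0.29), endothelial activation (23 measured, 1 risen, 1 fallen, 0.24) and angiogenesis (28 measured, 4 risen, 2 fallen, 0.77) did not pass.

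Fibroblast and mesenchymal markers rose in 4 of 16 knockout lung genes, with 4 risen and 2 fallen adjusted over the list alone. Col3a1 (1.57) and Mfap4 (1.21) were examples (camera adjusted p = 0.00092, and adjusted p = 0.27 with an estimated correlation). Monocyte and macrophage markers rose in 3 of 11, or 4 adjusted over the list alone, with C1qb at 0.77 and Mrc1 at 0.52 (camera adjusted p = 0.0096, and adjusted p = 0.38 with an estimated correlation). B cell markers fell in 2 of 10 by either count, Vpreb3 by 0.82 (camera adjusted p = 0.00091, and adjusted p = 0.42 with an estimated correlation). Club and ciliated cell markers fell in 5 of 15, or 8 adjusted over the list alone, with Gsta3 falling by 1.07 (camera adjusted p = 1.7e-05, and adjusted p = 0.27 with an estimated correlation). KO hypoxia 1 stood apart in these markers, with a mean deviation of -1.42 against 0.23 and -0.42 on the other arrays of its group, and in cardiac and skeletal muscle genes, with -3.10 against 0.62 and -0.54. No cardiac and skeletal muscle gene of 11 passed, nor adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.61 with an estimated correlation). Of 5 adipocyte genes none passed, and 1 fell adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.44 with an estimated correlation). KO hypoxia 1 and KO normoxia 1 stood apart in them as well, at -1.34 against -0.07 and -0.51, and at 1.33 against 0.27 and -0.17. Endothelial markers did not pass as a list (21 measured, 1 risen, 3 fallen, camera adjusted p = 0.11), while Plvap fell by 1.39 and Emcn rose by 0.72.

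In the knockout 1104 of 12571 genes passed, 624 up and 480 down (56.5% up, against 74.4% with the liver level as a covariate and 71.1% without KO normoxia 1 and 2), with 2616 at an unadjusted p under 0.05, and 223 rises and 199 falls of at least 2-fold. The groups did not overlap in 99.9% of the passing genes and 27.2% of all genes, against 10% by chance. The count was 697 without KO normoxia 1, 646 without KO hypoxia 1, 168 with the liver level as a covariate and 304 without KO normoxia 1 and 2, the arrays of highest liver level. With the covariate and without those arrays alike, the calls of the B cell, adipocyte, cardiac and skeletal muscle and glucocorticoid response lists were lost, as were those of Epas1, Nos3, Atf3, Acta2, Pfkl, Gapdh, Tap1, Stard4, Mfap4, C1qb, Mrc1, Vpreb3 and Emcn. The smooth muscle contractile list, Ccn1, Egr1, Tagln and Gsta3 lost theirs with the covariate alone, and the hypoxia and HIF target list without the arrays alone.

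**Figure D2:**
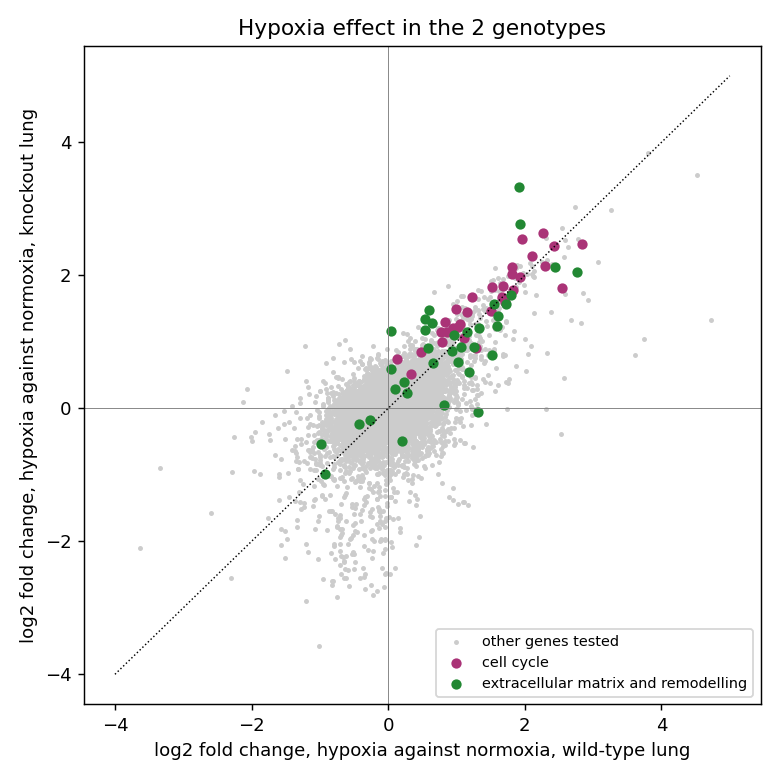
Log2 change under hypoxia in wild-type lung (horizontal axis) and in IL-4 knockout lung (vertical axis) for each of 12571 genes, with cell cycle genes in purple, extracellular matrix genes in green and other genes in grey; the dotted diagonal marks equal change. Across genes r was 0.557, and both coloured lists lay mostly above 0 on both axes.

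Whether the response to hypoxia differed between genotypes was tested as an interaction, the change in the knockout minus that in wild type. Eln differed by 1.41 (SE 0.18, adjusted p = 0.041). It rose from 9.27 ± 0.12 to 12.60 ± 0.16 in the knockout and from 10.50 ± 0.21 to 12.42 ± 0.01 in wild type (SD, n = 3). Fsip1, a gene named for a fibrous sheath protein of sperm, differed by -1.49 (SE 0.20, adjusted p = 0.041), going from 5.41 ± 0.09 to 6.38 ± 0.07 in wild type and from 6.53 ± 0.24 to 6.01 ± 0.21 in the knockout. For both genes the genotypes lay farther apart in room air than under hypoxia. No other gene passed. The 5 next smallest p-values belonged to Fhit (-1.48, adjusted p = 0.050), Npr3 (2.44, 0.063), Efcab6 (-1.45, 0.063), Mzb1 (-1.22, 0.066) and Cirbp (-1.46, 0.066). Retnla differed by -1.02 (SE 0.36, adjusted p = 0.24), Arg1 by -2.46 (0.11), Il4 by 0.80 (0.30), Nos3 by 0.76 (0.16) and Vegfa by 0.01 (0.99), and none of these passed.

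Lists differed between the genotypes although no member passed alone. B cell markers had a median difference of -1.04 over 10 measured genes, and 8 fell adjusted over the list alone (camera adjusted p = 9.3e-09, and adjusted p = 0.23 with an estimated correlation). T cell markers had -0.55 over 10, with 4 adjusted over the list alone (camera adjusted p = 6.9e-06, and adjusted p = 0.27 with an estimated correlation). For club and ciliated cell markers it was -0.45 over 15, with 4 adjusted over the list alone, beside the low values of KO hypoxia 1 (camera adjusted p = 0.00012, and adjusted p = 0.33 with an estimated correlation). Endoplasmic reticulum stress genes had 0.32 over 18, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.47 with an estimated correlation). Alveolar type 2 cell markers had 0.24 over 15 (camera adjusted p = 0.047, and adjusted p = 0.40 with an estimated correlation), endothelial markers 0.25 over 21 (camera adjusted p = 0.034, and adjusted p = 0.46 with an estimated correlation) and sterol synthesis genes -0.19 over 12 (camera adjusted p = 0.035, and adjusted p = 0.57 with an estimated correlation), with 0 members adjusted over the list alone in each. Cell cycle (median 0.21, camera adjusted p = 0.15), extracellular matrix (-0.03, 0.73), type 2 response (0.01, 0.62), hypoxia and HIF targets (0.01, 0.66), endothelial activation (-0.08, 0.24) and angiogenesis (-0.00, 0.80) did not pass.

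Only 2 of 12571 genes passed the interaction test in limma, while 1564 had an unadjusted p under 0.05. The count was 201 without WT normoxia 3, 10 without KO hypoxia 2, 7 without KO hypoxia 1, 1 without WT normoxia 2 or KO normoxia 3, and 0 without WT normoxia 1, WT hypoxia 1, 2 or 3, KO normoxia 1 or 2, or KO hypoxia 3. The calls of Eln and Fsip1 were lost on leaving out any of the arrays other than WT normoxia 3, KO hypoxia 1 and KO hypoxia 2, with an adjusted p of up to 0.203 over the alternatives. With the liver level as a covariate, and without KO normoxia 1 and 2, the count was 0, and the sterol synthesis and endothelial calls were lost, as was that of alveolar type 2 markers without those arrays.

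The overlap of both hypoxia responses was counted next, from comparisons that share no array. Genes that passed upward in both numbered 418, where independent lists would share 46.7, and genes that passed downward in both numbered 115, where they would share 20.7. Another 10 genes passed in opposite directions. Over the 2044 genes passing in either genotype, the changes had r = 0.680 across genes, which are not independent replicates, and 1657 of them (81.1%) went the same way.

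The genotypes were then compared in room air. The largest rises in the knockout were of liver transcripts: Ambp, which encodes a plasma proteinase inhibitor, stood at 12.30 ± 1.13 against 8.29 ± 0.69 in wild type (SD, n = 3), a 16.2-fold difference (log2 change 4.02, SE 0.47, adjusted p = 0.0012). Arg1 stood at 11.40 ± 1.10 against 7.82 ± 0.50, 12.0-fold higher. Among list members, 8 of 10 B cell and 7 of 10 T cell markers were higher, while 8 of 36 matrix, 7 of 12 heat shock and 2 of 9 smooth muscle genes were lower. All 5 of these list calls were lost with an estimated correlation, at adjusted p = 0.18, 0.24, 0.074, 0.27 and 0.27. Plac9a was 13.1-fold lower, at 7.92 ± 0.28 against 11.64 ± 0.17, and Tmem254a 6.67-fold lower, at 9.79 ± 0.47 against 12.53 ± 0.13. Il4 was 5.99-fold lower (log2 change -2.58, SE 0.22, adjusted p = 0.00016).

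Fga (4.01), Bhmt (3.92), Apoa1 (3.91), Itih3 (3.87), Apcs (3.85), Hpx (3.81) and Orm2 (3.71) were further rises on the log2 scale, and 32 of 36 measured liver genes rose, 6.23% of all rises. The mean deviation of the liver genes was 3.09, 1.59 and 1.11 on the KO normoxia arrays, and between -1.54 and 0.26 on the other 9 lung arrays. Among the latter, the KO hypoxia arrays, at -0.33, 0.19 and 0.26, lay above all wild-type arrays. Other falls were those of Fam107a (9.43-fold), Npr3 (5.80-fold), Fkbp5, a glucocorticoid-induced immunophilin (5.77-fold), and Hspb1, a small heat shock protein (4.47-fold). Il1r2, the decoy receptor of interleukin-1, fell by 3.36 on the log2 scale, a call lost without WT normoxia 1 or 2 or any KO normoxia array (adjusted p of up to 0.316 over the alternatives). Retnla differed by -0.00 (adjusted p = 0.99).

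**Figure D3:**
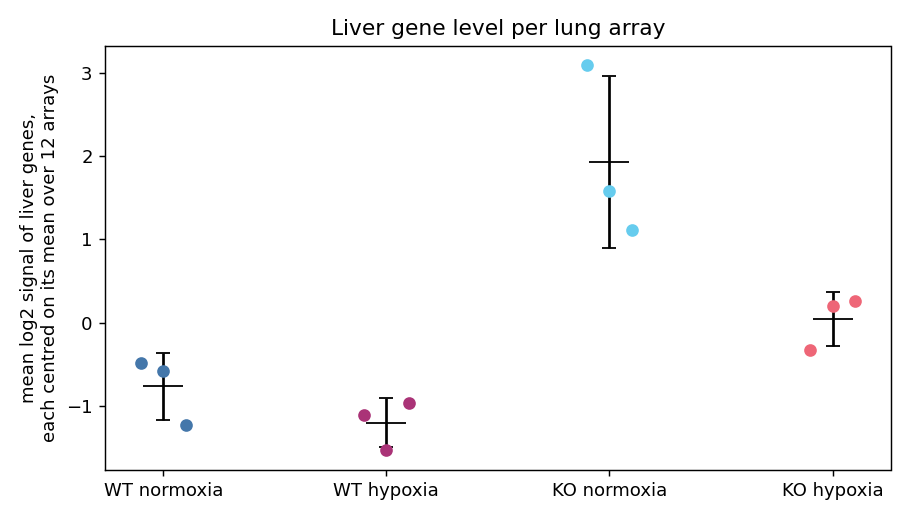
Mean log2 value of the measured liver genes, each centred on its mean over the 12 lung arrays, for every array (points), with the group mean and SD, n = 3 arrays per group. The KO normoxia arrays, at 3.09, 1.59 and 1.11, lay above the other 9, which ranged from -1.54 to 0.26.

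The liver level moved together with each of the lists that follow, since it was highest in the same group. B cell markers rose in 8 of 10, or 10 adjusted over the list alone, with Blk (1.99), Fcmr (1.64), Cd79b (1.62) and Cd79a (1.41) as examples (camera adjusted p = 2.2e-10, and adjusted p = 0.18 with an estimated correlation). T cell markers rose in 7 of 10, or 10 adjusted over the list alone, with Cd8b1 at 1.22 (camera adjusted p = 4.5e-08, and adjusted p = 0.24 with an estimated correlation). NK and cytotoxic cell markers rose in 2 of 12, or 5 adjusted over the list alone, with Eomes at least 1.41-fold higher (camera adjusted p = 0.017, and adjusted p = 0.41 with an estimated correlation). Heat shock genes fell in 7 of 12, with 8 fallen and 1 risen adjusted over the list alone, Hsph1 falling by 1.99 (camera adjusted p = 4.5e-06, and adjusted p = 0.27 with an estimated correlation). Extracellular matrix genes fell in 8 of 36, or 12 adjusted over the list alone, with Lox falling by 1.36, Eln by 1.23 and Mmp3 by 1.20 (camera adjusted p = 6.9e-06, and adjusted p = 0.074 with an estimated correlation). Endoplasmic reticulum stress genes fell in 3 and rose in 1 of 18, with 10 fallen and 1 risen adjusted over the list alone. Creld2 fell by 1.18 and Hspa5 by 0.92, while Atf3 rose by 1.15 (camera adjusted p = 4.3e-05, and adjusted p = 0.27 with an estimated correlation). Glucocorticoid response genes fell in 6 of 15, with 7 fallen and 2 risen adjusted over the list alone, Pdk4 by 1.99, Cdkn1a by 1.67 and Tsc22d3 by 0.94 (camera adjusted p = 0.00090, and adjusted p = 0.40 with an estimated correlation). Smooth muscle contractile genes fell in 2 of 9, or 4 adjusted over the list alone, Myocd by 0.93 and Lmod1 by 0.78 (camera adjusted p = 0.00041, and adjusted p = 0.27 with an estimated correlation). Circadian clock genes fell in 3 of 13, or 4 adjusted over the list alone, Ciart by 1.09 and Cry2 by 0.62 (camera adjusted p = 0.00052, and adjusted p = 0.16 with an estimated correlation). Sterol synthesis genes rose in 2 of 12, or 3 adjusted over the list alone (camera adjusted p = 0.0014, and adjusted p = 0.42 with an estimated correlation). The type 2 response list had 1 risen and 3 fallen of 24 and did not pass (camera adjusted p = 0.16).

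In room air 886 of 12571 genes passed, 514 higher and 372 lower in the knockout, with 2810 at an unadjusted p under 0.05, and 218 rises and 76 falls of at least 2-fold. The groups did not overlap in 99.5% of the passing genes and 24.5% of all genes, against 10% by chance. The count was 442 without WT normoxia 1, 411 without WT normoxia 2, 455 without KO normoxia 1 and 444 without KO normoxia 2. It was 57 without KO normoxia 1 and 2 together, and 2, namely Plac9a and Tmem254a, with the liver level as a covariate. Without those 2 arrays Ambp, Fga, Apoa1, Itih3, Arg1, Plac9a, Tmem254a, Il4, Npr3, Hspb1, Eln, Mmp3 and Hspa5 still passed, and the other genes named above did not. As lists, smooth muscle contractile, circadian clock and sterol synthesis genes lost their calls with the covariate, and sterol synthesis and NK and cytotoxic cell markers without the 2 arrays.

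Under hypoxia the genotypes differed in 7 genes, all lower in the knockout. Plac9a was 9.13-fold lower, at 8.56 ± 0.14 against 11.75 ± 0.34 (SD, n = 3; log2 change -3.19, SE 0.18, adjusted p = 6.4e-06), and Tmem254a 7.40-fold lower, at 10.01 ± 0.04 against 12.90 ± 0.08 (adjusted p = 1.1e-05). Gxylt2 was 5.45-fold lower, at 6.72 ± 0.10 against 9.16 ± 0.29 (adjusted p = 0.0028), and Il4 3.45-fold lower, at 5.60 ± 0.25 against 7.39 ± 0.22 (log2 change -1.79, adjusted p = 0.0088). Ccl19, a chemokine that guides lymphocytes and dendritic cells, was 2.39-fold lower (adjusted p = 0.037), Cyp1b1, a target of the aryl hydrocarbon receptor, 1.96-fold lower (adjusted p = 0.028), and Speer4d, which was detected on no KO hypoxia array, at least 2.72-fold lower (adjusted p = 0.027). Plac9a, Tmem254a, Gxylt2, Il4 and Ccl19 were lower in room air too. Plac9a and Tmem254a have close copies in the mouse genome, and whether their probes separate the copies was not tested.

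Of the genes that did not pass, the smallest p-values were those of the inducible chaperone Hspa1a (log2 change -2.74, adjusted p = 0.052), Clec10a (-0.82), Col14a1 (-0.78), Efcab6 (-0.91) and Vit, the last 4 at adjusted p = 0.074. Vit and Ccl2 were detected on no KO hypoxia array, and lay at least 1.91-fold and at least 2.11-fold lower there (adjusted p = 0.074 and 0.13). Retnla differed by -1.02 (adjusted p = 0.20), Ccl11 by -0.86 (0.16) and Vcam1 by -0.45 (0.20).

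Although no list member passed alone, 16 lists passed, 1 of them with both settings of the correlation. That one was extracellular matrix, with a median of -0.23 over 36 genes and 9 lower adjusted over the list alone (camera adjusted p = 8.1e-10, and adjusted p = 0.025 with an estimated correlation). Heat shock genes had a median of -0.52 over 12, with 9 lower adjusted over the list alone (camera adjusted p = 5.6e-14, and adjusted p = 0.095 with an estimated correlation). Circadian clock genes had -0.33 over 13, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.3e-05, and adjusted p = 0.095 with an estimated correlation). Type 2 response genes had -0.14 over 24, with 5 lower adjusted over the list alone (camera adjusted p = 0.0047, and adjusted p = 0.12 with an estimated correlation). Endothelial activation genes had -0.14 over 23, with 5 lower adjusted over the list alone (camera adjusted p = 0.00091, and adjusted p = 0.27 with an estimated correlation). Monocyte and macrophage markers had -0.38 over 11 and 4 lower adjusted over the list alone (camera adjusted p = 8.2e-05, and adjusted p = 0.24 with an estimated correlation). Fibroblast and mesenchymal markers had -0.25 over 16 and 3 lower adjusted over the list alone (camera adjusted p = 0.00018, and adjusted p = 0.23 with an estimated correlation). Club and ciliated cell markers (-0.39 over 15, camera adjusted p = 5.9e-06, and adjusted p = 0.27 with an estimated correlation) and cardiac and skeletal muscle genes (-0.97 over 11, camera adjusted p = 0.010, and adjusted p = 0.60 with an estimated correlation) had 0 members adjusted over the list alone, and both were lowest on KO hypoxia 1.

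Downward lists also included smooth muscle contractile genes (-0.25 over 9, with 1 lower adjusted over the list alone, camera adjusted p = 0.00091, and adjusted p = 0.27 with an estimated correlation) and glucocorticoid response genes (-0.28 over 15, with 2 lower adjusted over the list alone, camera adjusted p = 0.0015, and adjusted p = 0.42 with an estimated correlation). Further ones were interferon genes (-0.16 over 27, camera adjusted p = 0.0011, and adjusted p = 0.57 with an estimated correlation) and endoplasmic reticulum stress genes (-0.15 over 18, camera adjusted p = 0.0043, and adjusted p = 0.44 with an estimated correlation). Upward lists were alveolar type 2 cell markers (0.26 over 15, with 1 higher adjusted over the list alone, camera adjusted p = 7.1e-05, and adjusted p = 0.14 with an estimated correlation), NK and cytotoxic cell markers (0.35 over 12, with 1 higher adjusted over the list alone, camera adjusted p = 0.0032, and adjusted p = 0.31 with an estimated correlation) and cell cycle genes (0.10 over 31, with 0 adjusted over the list alone, camera adjusted p = 0.048, and adjusted p = 0.64 with an estimated correlation). No interferon or endoplasmic reticulum stress gene passed adjusted over the list alone.

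Among 12571 genes tested in hypoxic lung, 945 had an unadjusted p under 0.05 beside the 7 that passed in limma. The groups did not overlap in all 7 and in 13.7% of all genes, against 10% by chance. The count was 12 without WT hypoxia 3, 38 without KO normoxia 1, 4 without KO hypoxia 1, 3 without KO hypoxia 2, 3 without KO hypoxia 3 and 2 with the liver level as a covariate. Calls in the other direction appeared in some settings, 59.3% of the 27 genes with only the 2 groups compared and 55.3% of the 38 without KO normoxia 1 being higher in the knockout. Il4 did not pass without KO hypoxia 2 (adjusted p = 0.0567) or KO hypoxia 3 (adjusted p = 0.0752), nor with the liver level as a covariate. The calls of Speer4d (any KO hypoxia array), Ccl19 (any WT normoxia or KO hypoxia array, WT hypoxia 1 or 2) and Cyp1b1 (any WT or KO hypoxia array, KO normoxia 2) were lost on leaving out the arrays in brackets, with adjusted p of up to 0.171, 0.230 and 0.210 over the alternatives. Without any 1 of the WT hypoxia arrays Speer4d was detected on too few arrays to be tested, so its call was lost there as well. The calls of Plac9a and Tmem254a held in all 23 settings. With the covariate the cell cycle, smooth muscle contractile and alveolar type 2 calls were lost as well.

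Within 10 Mb of Il4, where DNA of the strain that gave the targeted embryonic cells can persist, 5 of 161 genes passed in room air against 803 of 11354 elsewhere (Fisher's exact test, two-sided, p = 0.0597), and 0 of 161 against 6 elsewhere passed under hypoxia (p = 1).

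The last comparison asked what recombinant IL-4 changed in cultured PMVEC after 24 h. Ccl11, the eosinophil chemokine eotaxin-1, rose 7.85-fold, from 6.16 ± 0.03 to 9.13 ± 0.16 on the log2 scale (SD, n = 3; log2 change 2.97, SE 0.11, adjusted p = 1.0e-07). Aif1l rose 5.68-fold, from 9.02 ± 0.11 to 11.52 ± 0.17, and Serpina3n, a secreted serine protease inhibitor, 3.79-fold, from 9.53 ± 0.07 to 11.45 ± 0.12. Edn1, the vasoconstrictor endothelin-1, rose 2.87-fold, from 5.59 ± 0.06 to 7.12 ± 0.10. Falls were smaller, the largest being that of Fst, the activin antagonist follistatin, 2.12-fold, from 9.97 ± 0.08 to 8.88 ± 0.13.

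Other rises in PMVEC were those of Pcolce2 (3.78-fold), the immediate early gene Fos (3.50-fold, from 5.96 ± 0.14 to 7.77 ± 0.29), Ccl8 (3.03-fold), Serpinb1a (log2 change 1.66), Krt19 (0.97) and Aldh1a1 (0.91). The monocyte chemokines Ccl7 and Ccl2 rose by 1.01 (adjusted p = 0.00047) and 0.93 (adjusted p = 0.0015). Lpl fell by 0.94, Samd9l by 0.91 and Prkg2 by 0.91. Vcam1 changed by 0.08 (adjusted p = 0.89), Vegfa by -0.24 (0.56), Icam1 by -0.11, Selp by 0.04, Kdr by 0.02 and Nos3 by -0.15, and none of these passed. Kdr was dim, with a raw signal of 65.45 ± 3.68 (SD, n = 6) and detection on 5 of 6 arrays, so its value cannot show the absence of a response.

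Of the type 2 response list 9 genes were measured in PMVEC, of which 3 rose by either count, including adjusted over the list alone, and 6 did not pass. Ccl11 and Cish, a suppressor of cytokine signalling (0.86), were examples (camera adjusted p = 5.5e-06, and adjusted p = 0.11 with an estimated correlation). Immediate early genes rose in 4 of 13, or 7 adjusted over the list alone (camera adjusted p = 5.9e-06, and adjusted p = 0.33 with an estimated correlation). Interferon genes fell in 6 of 21, or 8 adjusted over the list alone, with Isg15 falling by 0.97, Ifit3 by 0.81, Rsad2 by 0.70 and Oasl2 by 0.66 (camera adjusted p = 6.2e-08, and adjusted p = 0.22 with an estimated correlation). These calls were lost without vehicle 1, those of Ifit3 also without vehicle 3 or rIL-4 1 or 2, of Rsad2 without vehicle 2 or rIL-4 2 or 3, and of Oasl2 without vehicle 2. Over the alternatives their adjusted p reached 0.135, 0.188, 0.116 and 0.239. Fibroblast and mesenchymal markers had a median of -0.16 over 11, with 2 fallen adjusted over the list alone and 0 over all genes (camera adjusted p = 0.027, and adjusted p = 0.27 with an estimated correlation). Endothelial activation (16 measured, 2 risen, camera adjusted p = 0.29), angiogenesis (17 measured, 1 risen, 1 fallen, 0.39) and endothelial markers (5 measured, 1 risen, Plvap at 0.88, camera adjusted p = 0.37) did not pass.

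In PMVEC 151 of 9017 genes passed, 102 up and 49 down, with 1014 at an unadjusted p under 0.05, and 29 rises and 1 fall of at least 2-fold. The split by direction depended on the scaling, with 142 up and 23 down after a median shift, and 276 up and 22 down in the deposited log2 table. The groups did not overlap in 100% of the passing genes and 16.4% of all genes, against 10% by chance. The count was 74 without vehicle 1, 73 without vehicle 2, 83 without vehicle 3, 92 without rIL-4 2 and 82 without rIL-4 3. The calls of Lpl, Samd9l, Prkg2 and Plvap were lost with no filter on dim probes. Of 21 endothelial markers, 3 (Eng, Egfl7 and Ramp2) were detected on all 6 PMVEC arrays, against all 21 on the 12 lung arrays, while 10 of 16 fibroblast and mesenchymal markers were detected on all 6.

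**Figure D4:**
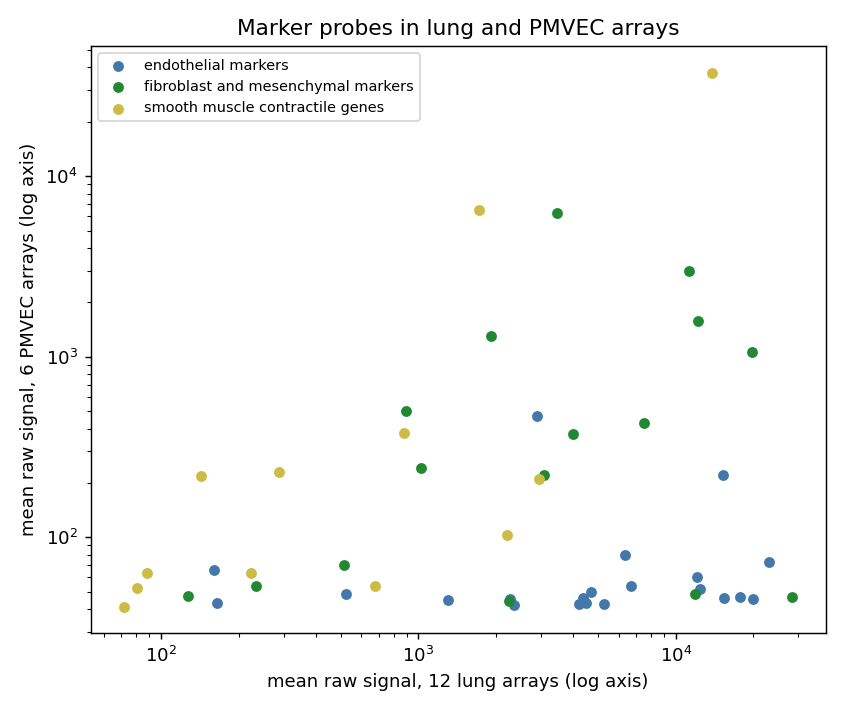
Mean raw signal of marker genes over 12 lung arrays (horizontal axis) and over 6 PMVEC arrays (vertical axis), both axes logarithmic, with endothelial markers in blue, fibroblast and mesenchymal markers in green and smooth muscle contractile genes in yellow. The tables were not normalized together, and signals of different probes do not rank their transcripts; all 21 endothelial markers were detected on the 12 lung arrays and 3 of them on all 6 PMVEC arrays.

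The genes that responded to IL-4 in PMVEC were followed as sets into the lung comparisons. The set that rose held 102 genes, 92 of them measured in lung, and the set that fell 49, of which 48 were measured. The risen set was lower in the knockout under hypoxia, with a median of -0.04 (camera adjusted p = 0.0375, and adjusted p = 0.101 with an estimated correlation), and the fallen set was higher in hypoxic than in normoxic knockout lung, with a median of 0.16 (camera adjusted p = 0.0375, and adjusted p = 0.563 with an estimated correlation). Neither passed when the 100 genes of smallest p in each direction were taken instead (adjusted p = 0.0624 and 0.123). The other 8 tests of these sets did not pass, the smallest adjusted p being 0.0877 for the fallen set in wild-type hypoxia. For the risen set in the interaction, the median was 0.04 while the test pointed down (adjusted p = 0.70), and for the fallen set between genotypes under hypoxia the median was 0.01 while the test pointed down.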

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

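The tests of liver RNA, of the falls of Plac9a and Tmem254a, of normalization, of the marker genes in PMVEC and of another locus were chosen after the result was seen, as was the omission of 2 arrays, and the liver covariate was added once liver genes had been seen among the calls, before its own result was.

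The response to hypoxia differed between genotypes in 9 results of the interaction test. Eln differed by 1.41, its rise being larger in the knockout, and Fsip1 by -1.49. For both, the genotypes lay farther apart in room air than under hypoxia, and KO normoxia was also the group of highest liver level. Among lists, the median difference was -1.04 for B cell markers, -0.55 for T cell markers, -0.45 for club and ciliated cell markers, -0.19 for sterol synthesis, 0.32 for endoplasmic reticulum stress, 0.24 for alveolar type 2 cell markers and 0.25 for endothelial markers. Between genotypes, the B cell, T cell and sterol synthesis lists passed in room air alone. The club and ciliated cell and alveolar type 2 lists passed under hypoxia alone, endoplasmic reticulum stress in both and endothelial markers in neither. The 2 gene calls were lost on leaving out any array other than WT normoxia 3, KO hypoxia 1 and KO hypoxia 2, with adjusted p of up to 0.203, and the 7 list calls were lost with an estimated correlation. Of 100 splits of the 12 lung arrays, 10 gave at least as many genes as the 2 of the real interaction, so chance was not excluded. The highest other count, 504 genes, came from the split that exchanged the genotypes of the hypoxic arrays alone, and which therefore measured the sum of the genotype differences in both oxygen conditions. Of the 9 other splits with as many genes, 8 kept the genotypes of the 6 normoxic arrays, so that the difference between genotypes in room air enters them too. Without WT normoxia 3 the count was 201.

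For the other comparisons 10 splits of the 6 arrays exist, too few for a share under 0.05. The real split gave the highest count in each, 1 of 10. It was 1483 against a highest other of 0 for hypoxia in wild type, 1104 against 0 for hypoxia in the knockout, 886 against 1 for genotype in room air, 7 against 1 for genotype under hypoxia, and 151 against 0 for PMVEC. On leaving out 1 array, the wild-type count was 922 (WT normoxia 1), 890 (WT normoxia 2), 910 (WT hypoxia 1) or 984 (WT hypoxia 2), and the knockout count 697 (KO normoxia 1) or 646 (KO hypoxia 1). In room air it was 442 (WT normoxia 1), 411 (WT normoxia 2), 455 (KO normoxia 1) or 444 (KO normoxia 2), and under hypoxia 12 (WT hypoxia 3), 38 (KO normoxia 1), 4 (KO hypoxia 1) or 3 (KO hypoxia 2 or 3). In PMVEC it was 74, 73 and 83 without vehicle 1, 2 and 3, and 92 and 82 without rIL-4 2 and 3.

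Liver transcripts stood high in KO normoxia, Fga at 15.13, 13.43 and 12.71 on its arrays against 8.85 to 10.20 in WT normoxia. On the KO hypoxia arrays the mean liver level, at -0.33, 0.19 and 0.26, also lay above all wild-type arrays, at -1.54 to -0.48. No liver gene passed between genotypes under hypoxia, where the median difference was 1.33. For KO normoxia, normalization and background correction are argued against, since 88.9% of the measured liver genes were at least 2-fold higher in raw signal than in WT normoxia. A candidate explanation is RNA of liver in the KO normoxia samples. Over 12 arrays Arg1, left out of the list, moved with the liver level within groups, as 1 relation computed (Pearson r = 0.922, permutation p = 7e-05, and Spearman rho = 0.776, permutation p = 0.0044). Without KO normoxia 1 and 3 r was 0.736. The permutations moved deviations freely between groups of unlike spread, so both p-values are approximate. Arg1 is itself transcribed in liver, so any cause that raised liver genes together would give this relation. That 36 of the 40 genes were measured does not bear on it, since detection on 3 arrays sufficed, which KO normoxia alone could supply. With the liver level as a covariate 2 of 886 calls stayed, which met what had been set out for liver RNA as the source of all calls; yet the covariate widened the error 2.20 times, which alone would leave 1 call, and the decision to leave the question open on that ground was made after the count was seen. Among 854 other calls the median size went from 0.756 to 0.595 and the error from 0.161 to 0.332, 751 (87.9%) keeping their direction. As 14.2% of the spread in liver level lay within groups, the covariate cannot tell liver RNA from a genotype effect for these calls. The exceptions were Plac9a and Tmem254a, for which liver RNA is argued against, since both passed with the covariate, at -3.68 or lower. For Il4 the covariate does not decide, since Il4 passed with it in neither oxygen condition. In KO hypoxia Il4 lay below all wild-type arrays, but the liver level there lay above all of them, so the 2 cannot be told apart. Added liver RNA would lower lung transcripts alike, yet 0 of 10 alveolar type 1 markers passed (median 0.03), against a median of -0.33 for matrix genes. Among other cell types the median was -0.02 for alveolar type 2, -0.17 for monocyte and macrophage, -0.20 for endothelial and -1.01 for neutrophil markers, but 1.22 for B cell and 0.69 for T cell markers. The alveolar medians near 0 argue against a common dilution as the sole source of falls of at least 2-fold. No test of this was run, and rises and smaller falls stay open.

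Most endothelial markers lay near background in PMVEC, with Pecam1 (raw signal 43.2 ± 4.44, SD, n = 6), Vwf (42.8 ± 3.65) and Cdh5 (44.8 ± 3.32) detected on 0 of 6 arrays, while Vim (6215 ± 624) and Acta2 (37464 ± 3291) were detected on all 6, as were 7 of 12 smooth muscle genes with Acta2 among them, though Myh11 was detected on 0; signals of different probes do not rank their transcripts. Probes that cannot report these genes are argued against, since 21 of 21 were detected on all 12 lung arrays. Values given to the wrong probe are argued against too, since no more than 3 of 21 were detected on all 6 arrays through any of their probes in the non-normalized and log2 tables. Cultures made up mostly of mesenchymal cells are a candidate explanation, as 10 of 16 fibroblast markers were detected against those 3 of 21 (Fisher's exact test, two-sided, p = 0.00464). Markers of a list are not independent replicates, so this p-value only describes the lists. The fibroblast markers Tcf21, Inmt, Mfap4, Lum and Fap were detected on 0 of 6 arrays. Nor was the share particular to fibroblast markers, 6 of 11 alveolar type 1 markers also being detected, and the labels call the cells endothelial. A loss of endothelial transcripts during culture stays open and untested, and the design gives no group that bears on it.

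Plac9a, Tmem254a, Gxylt2, Il4 and Ccl19 were lower in the knockout in room air and under hypoxia, with log2 differences of -3.72 and -3.19 for Plac9a, -2.74 and -2.89 for Tmem254a, -1.16 and -2.45 for Gxylt2, and -0.76 and -1.26 for Ccl19, whose call under hypoxia was lost (adjusted p of up to 0.230) without any WT normoxia or KO hypoxia array or WT hypoxia 1 or 2, as that of Il4 was without KO hypoxia 2 (0.0567) or 3 (0.0752). Strain DNA kept next to Il4 is argued against for this set, with 0 of the other 4 genes within 10 Mb of Il4; in room air alone 5 of 161 genes there passed, 3.11% against 7.07% elsewhere (Fisher's exact test, p = 0.0597), and the restriction to genes called in both conditions was made after that was seen. A genomic difference at another locus is a candidate explanation for Plac9a and Tmem254a, which lie next to each other on chromosome 14, the 1 pair of those 4 genes within 10 genes of each other (permutation p = 0.0068 over 10000 random sets of as many tested genes). An effect of IL-4 on these genes stays open. The pair of neighbours had been seen before its test was chosen, so the permutation p only describes it. With the liver level as a covariate, Gxylt2, Il4 and Ccl19 passed in neither oxygen condition.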

How the results depend on the processing

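The liver covariate and the omission of KO normoxia 1 and 2 were chosen after the result was seen. Counts that moved by over 1.5 times are given first, and the cause was not tested unless stated. For hypoxia in the knockout (1104) the count was 1710 with array weights, 168 with the liver covariate and 304 without the 2 arrays. For the interaction (2) it was 74 with no background correction, 27 with a median shift, 11 with all 18 arrays normalized together, 32 in the deposited log2 table, 140 with trended and robust variance, 214 with array weights, and 0 with no filter, with the covariate or without the 2 arrays. For genotype in room air (886) it was 1776 with array weights, 415 with only the groups compared, 2 with the covariate and 57 without the 2 arrays. For genotype under hypoxia (7) it was 18 with no background correction, 14 with a median shift, 20 in the log2 table, 21 with trended and robust variance, 45 with array weights, 27 with only the groups compared and 2 with the covariate. For PMVEC (151) it was 87 with all 18 arrays together, 298 in the log2 table, 75 with no filter and 257 with array weights. The count for hypoxia in wild type stayed within 1.5 times under each alternative that kept all arrays. Without the 2 arrays fewer samples were left, and the lone KO normoxia array is assumed to vary like the other groups. Leaving out 1 array gave 890 to 1811, 646 to 1194, 0 to 201, 411 to 1238, 3 to 38 and 73 to 117 genes in the 6 comparisons.

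The share of rises moved in some settings. It was 73.9% against 63.4% in the log2 table for hypoxia in wild type. For hypoxia in the knockout it was 56.5%, against 74.4% with the liver covariate and 71.1% without the 2 arrays, and for genotype in room air 58.0%, against 70.2% without the 2 arrays and 0% of 2 genes with the covariate. In PMVEC it was 67.5%, against 86.1% with a median shift, 92.6% in the log2 table, 79.3% with all 18 arrays together and 81.3% with no filter. For genotype under hypoxia it was 0%, against 16.7% with no background correction, 28.6% with a median shift, 20% in the log2 table, 33.3% with array weights, 59.3% with only the groups compared and 55.3% without KO normoxia 1. For the interaction it was 50% of 2 genes, against 22.2% with a median shift, 27.3% with all 18 arrays together and 12.5% in the log2 table, the value with no background correction lying between the last 2. With the liver covariate the sign turned for Hpx (0.31), Orm2 (0.039), Orm1 (0.055) and Tat (0.40) in knockout hypoxia and for Apcs (-0.89), Hpx (-0.70), Orm2 (-0.26) and Notch4 (0.074) in the room air comparison, with no such value past the threshold. The correlation of both hypoxia responses was 0.680 over genes passing in either. The PMVEC sets in lung had adjusted p = 0.563 and 0.101 with an estimated correlation, and 0.123 and 0.0624 with 100 genes per direction, for the fallen set in knockout hypoxia and the risen set between genotypes under hypoxia.

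Over all combinations of a named gene and an omitted array, the call was lost in 475, gained in 26, turned in 0 and the same in 3954. The last count also holds named genes that passed neither before nor after the omission, so it is not a count of calls that held. A turn was counted only for genes that passed, and genes no longer tested after an omission were left out. The covariate ended 125 and the omission of 2 arrays 95. An estimated correlation ended 62 list calls and left 5. No paired analysis was possible because the sample numbers in the labels run on from group to group, so that the groups compared share none. In PMVEC the numbers run on with a gap between vehicle and rIL-4. They do not show whether vehicle and rIL-4 samples came from the same cultures, so a pairing there was neither tested nor excluded. A block by chip was not run because the files used here give no chip. Probes not above background on at least 3 arrays were left out, and at a log2 change of 0.5 the simulated recovery over all tested genes was between 4% and 64%, not split by brightness.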

Other observations

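The genes named here were taken by the rule stated for named genes, and of the tests here only the liver covariate and the omission of 2 arrays were chosen after the result was seen.

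Lyve1, the hyaluronan receptor of lymphatic endothelium and some macrophages, fell by 1.97 under hypoxia in wild type (adjusted p = 4.8e-06), a 3.92-fold fall, while Ccl21a, a chemokine of lymphatic vessels, rose by 1.56. Ctsk, a collagen-degrading cathepsin, rose by 1.33. Within the circadian clock list Arntl fell by 1.10 and Cry2 by 0.64, and the list did not pass (13 measured, 1 risen, 2 fallen, camera adjusted p = 0.11). Heat shock genes went both ways, Hspa1a by 2.52, Dnajb1 by 1.31 and Hspb1 by -1.65, and as a list did not pass (12 measured, 2 risen, 1 fallen, camera adjusted p = 0.28). Cardiac and skeletal muscle genes had a median of -1.16 and did not pass either (11 measured, camera adjusted p = 0.052).

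In knockout lung under hypoxia, Cd34, a marker of endothelium and stromal precursors, rose by 1.04, and Ccl21a by 1.19. The endothelial genes Esm1 and Cx3cl1 fell by 1.69 and 0.97. These 4 calls held with the liver level as a covariate and without KO normoxia 1 and 2.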
